A study of Mus musculus with 8 samples.

How the data were processed

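Total RNA from liver of male C57Bl/6J mice was amplified and labelled with Cy3 for single-colour Agilent arrays with the low-input labelling kit, per the labels' protocols. The 8 arrays fall into 4 diet groups of 2, per the labels: BD_HF, LF_HF, LF_LF and VAD_VAD. The labels number the samples within a group and do not state that each came from its own animal, so p-values measure the spread between these samples. Every array had a sample, and 0 columns were left without one.

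The arrays hold the Agilent design 014868, and images were read with Feature Extraction 10.7.3.1, per the file headers. The deposited array files give the processed signal as an intensity on the linear scale after spatial detrending, local background handling and multiplicative detrending, with a surrogate value for spots near background, per the file headers. They also give raw mean and local background intensities, per the file headers. No scaling between arrays is recorded in the headers. The deposited series table held the same processed intensity, rounded, with a largest relative difference of 0.497%, so it was on the linear scale, not log2, and not centred. Its column medians were 26.3 and 19.7 in BD_HF, 184 and 17.3 in LF_HF, 30.8 and 29.2 in LF_LF, and 26.1 and 19.9 in VAD_VAD. The submitters' processing notes name limma without a version or role, and the version is not given in the sources used here.

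Each array held 45018 spots, of which 43379 were gene probe spots, 1486 positive controls and 153 negative controls; 0 spots were saturated. Spots of the same probe were averaged, giving 41174 gene probes. A reference symbol was found for 28223 of them (68.55%), and 1471 of those symbols differed from the name in the file. Symbols came from a GRCm38.p6 gene table, used for names alone, and probe positions are printed in mm9, the build in the file headers. Families with near-identical members, such as the Cyp2c, Hsd3b, Gsta, Raet1 and Hba genes, can share signal between probes, so the member named is uncertain. LF_HF replicate 1 differed from the other arrays: 952 tested genes had no value on it, 2707 of its spots were outliers against 46 to 316 elsewhere, its extraction quality result differed from that of the other 7, and the slope of its spike-in controls was 0.962 against 0.993 to 1.01. The SD of the difference between replicates over genes was 0.555 in BD_HF, 1.47 in LF_HF, 0.408 in LF_LF and 0.711 in VAD_VAD.

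From the deposited intensities, log2 values were computed here, and the 75th percentile of each array was subtracted. Probes were kept when well above background on both arrays of at least 1 group, which left 26224, and the probe with the highest mean represented each gene, for 17354 genes. Of these, 16248 had a value on every array. Group means were compared with limma 3.58.1 (lmFit and eBayes, 4 residual and 3.42 prior degrees of freedom) in R 4.3.3 on all 8 arrays, with Benjamini-Hochberg adjustment per comparison and a threshold of adjusted p under 0.05. The comparisons were BD_HF minus LF_HF, LF_HF minus LF_LF, and VAD_VAD minus LF_LF, as the study's design states them, with the last given as deficient minus sufficient. Tables were handled with data.table, version 1.17.8, and jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

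A gene was called below background in a group when 0 of its arrays were well above background. Its fold is then given as a bound, with the group set to the lowest log2 value that was well above background on each array, and written as at least that fold. No fold is given where both groups were below.

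For 30 lists of genes written beforehand (metabolic, stress, immune, sex-biased, imprinted, cell cycle and cell-type genes), limma's camera tested whether members moved against the other genes, with a preset correlation of 0.01, adjusted over the 30 lists. All 30 had at least 5 measured genes. The test was repeated with a correlation estimated per list. Fry asked a different question, whether the members of a list as a set shifted from no change in one direction, without comparing them with the other genes. With an estimated correlation 0 lists passed in any comparison, and the smallest adjusted p was 0.262, 0.137 and 0.0938 in the order above. A call lost in that setting does not by itself show that members vary together. Neutrophil markers, at an estimated correlation of −0.0204, went from a camera adjusted p of 0.000282 to 0.162 in VAD_VAD minus LF_LF. The sign of the test, the median and the mean differed in 6, 3 and 2 lists, and 0 of those were called.

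Comparisons, lists, threshold, alternatives and the rule for named genes were fixed before the data were examined. Named were, per comparison and direction, the 10 genes with the largest change among those called whose replicates did not overlap, leaving out provisional names (38 of the called genes in LF_HF minus LF_LF and 8 in VAD_VAD minus LF_LF). Where fewer than 5 were called in a comparison, the 5 with the smallest p in each direction were named. Added were up to 4 called members per list with the smallest p, and a fixed set of lipid, bile acid and acute phase genes, with retinoid genes for vitamin A and imprinted and fetal genes for the maternal diet; 1 of the genes so named is not reported here. Members quoted because they passed over a list alone, and further pairs of groups, were chosen after their values were seen.

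The arrays lay on 2 slides, each with 1 array of every group and all arrays of 1 replicate number, per the file headers. Slide was tested as a block. For called lists the median within each slide is given where the medians of the slides differed in sign or by a factor of 2 or more, and the median without LF_HF replicate 1 where it differed from the reported one in sign or by a factor of 1.5 or more.

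The procedure was tested on simulated data with the spread of these arrays, 16248 genes, 200 of them changed, in 20 datasets. For BD_HF minus LF_HF it recovered 2.69%, 34.6% and 87.7% of changes of log2 1, 2 and 4, and 33.1% of its calls were false. For LF_HF minus LF_LF it recovered 2.09%, 33.0% and 87.4%, with 28.2% false, and for VAD_VAD minus LF_LF 0%, 23.1% and 86.6%, with 0.480% false. In the 2 comparisons that use LF_HF the share of false calls was above the nominal 5%. A list of 20 genes shifted by log2 1 was called in 20 of 20 datasets in each comparison at the preset correlation. With an estimated one it was called in 2, 2 and 16 of 20. Unshifted lists were called 1, 0 and 1 times at the preset correlation. Simulated genes varied independently, while correlations estimated in the real lists ran from −0.0204 (neutrophil markers) to 0.817 (hepatocyte markers). The simulated lists therefore cannot show how often the preset test errs where members vary together.

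Alternatives covered normexp background correction with an offset of 50, quantile scaling, the median in place of the percentile, the series table, other filters and probe summaries, slide and replicate number as blocks, fits to the compared groups alone, other variance settings and thresholds, and leaving out each array. Cyclic loess and array weights were added after seeing the data. Leaving out an array leaves 1 in its group, which is assumed to vary like the other groups.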

Results

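Gene expression in the liver of male C57Bl/6J mice, an inbred laboratory strain, was measured at 14 weeks of age with 8 single-colour Agilent arrays, 2 per diet group. Each group is named here by the diet of the dam and then the diet after weaning. BD_HF offspring came from dams on a standard breeder diet and were weaned onto a high fat diet with 60% of energy from fat. LF_HF offspring received the same high fat diet, and their dams were moved at embryonic day 10.5 to a defined low fat diet with 12% of energy from fat and sufficient vitamin A. LF_LF animals had this low fat, vitamin A sufficient diet in both periods, and VAD_VAD animals had a vitamin A deficient low fat diet in both periods. Livers were collected after a fast of 4 h. Values are differences between group means on the log2 scale with their standard error (SE), and n = 2 arrays per group for every value unless another number is given.

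After the probe filter, 26224 of 41174 probes were kept, and 17354 genes were tested in each comparison. The 75th percentile of the processed signal was 237 and 225 in BD_HF, 496 and 195 in LF_HF, 291 and 296 in LF_LF, and 248 and 224 in VAD_VAD. On LF_HF replicate 1, 82.2% of the probes were well above background, against 56.5% to 64.2% on the other 7 arrays. Pearson correlations between the 2 replicates were 0.988 in BD_HF, 0.917 in LF_HF, 0.992 in LF_LF and 0.977 in VAD_VAD. The number of arrays limits the precision of every value.

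**Figure D1:**
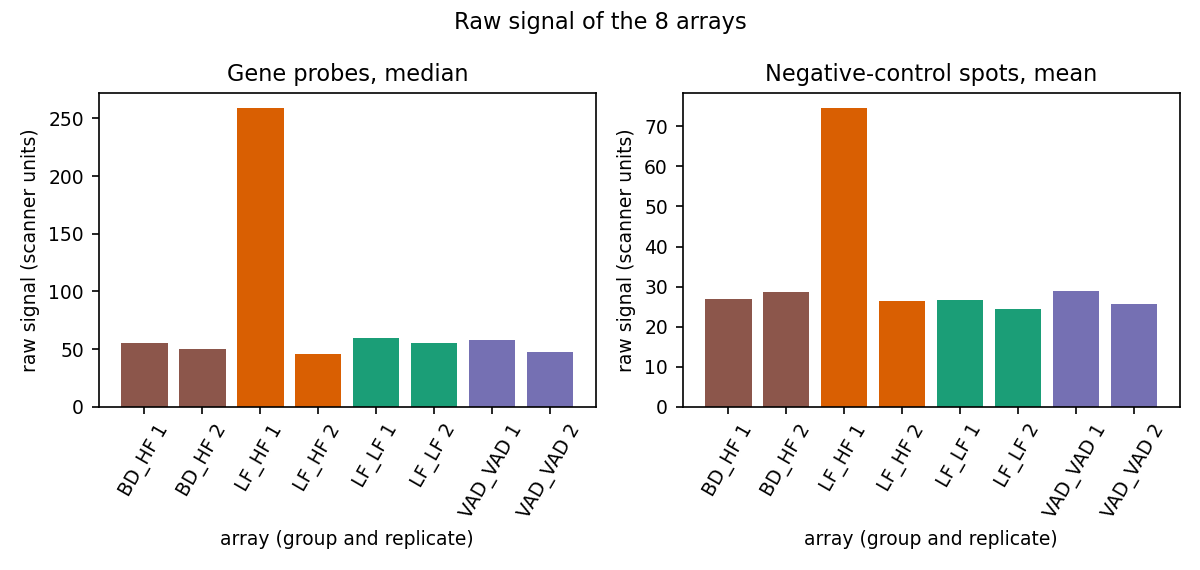
Raw signal of each of the 8 arrays, in scanner units, for gene probes and negative-control spots. The median of the gene probes was 259 on LF_HF replicate 1 and 45.8 to 59.4 on the other arrays.

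VAD_VAD minus LF_LF asks what a vitamin A deficient low fat diet, maternal and after weaning, changes in the liver against the sufficient one. Cyp26b1, an enzyme that clears retinoic acid, fell by 7.67 on the log2 scale (SE 0.948, adjusted p = 0.0264), and only 1 of the 2 deficient arrays was above background. Lrat, which esterifies retinol for storage, fell by 5.81 (SE 0.662, adjusted p = 0.0206, 56.0-fold), again with 1 of 2 deficient arrays above background. Fabp5, a carrier of fatty acids and retinoic acid, rose from below background on both LF_LF arrays (adjusted p = 0.0179), a rise of at least 9.74-fold.

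Other retinoid genes did not pass. Cyp26a1, the main hepatic enzyme for retinoic acid clearance, was above background on 0 of 2 deficient arrays, at least 59.2-fold lower (adjusted p = 0.0642). Rarb, a retinoic acid receptor gene that is itself induced by retinoic acid, differed by −3.63 (SE 0.605, adjusted p = 0.0592). Rbp4, which carries retinol in plasma, differed by 0.37 (SE 0.398, adjusted p = 0.790). Stra6l, a liver receptor for that carrier, differed by 0.28 (SE 0.375), and Dhrs3, which reduces retinaldehyde, by −0.17 (SE 0.428). Of the 14 measured retinoic acid targets, 0 rose, 3 fell and 11 did not pass over all genes; adjusted over the list alone, 6 fell. The median member differed by −0.97, or −0.66 with signals below background set to the array's bound, and the list fell (adjusted p = 1.23e-06; adjusted p = 0.162 with an estimated correlation). Of the 27 retinoid handling genes, 1 rose and 3 fell, and 2 rose and 4 fell adjusted over the list alone; the list did not pass (adjusted p = 0.538), with a median of 0.24 and a mean of −0.59. In mm9, the build named in the file headers, the Cyp26b1 probe lay on chromosome 6 at 84521952 to 84522011, the Lrat probe on chromosome 3 at 82699609 to 82699668. The Cyp26a1 probe lay on chromosome 19 at 37775566 to 37775625.

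**Figure D2:**
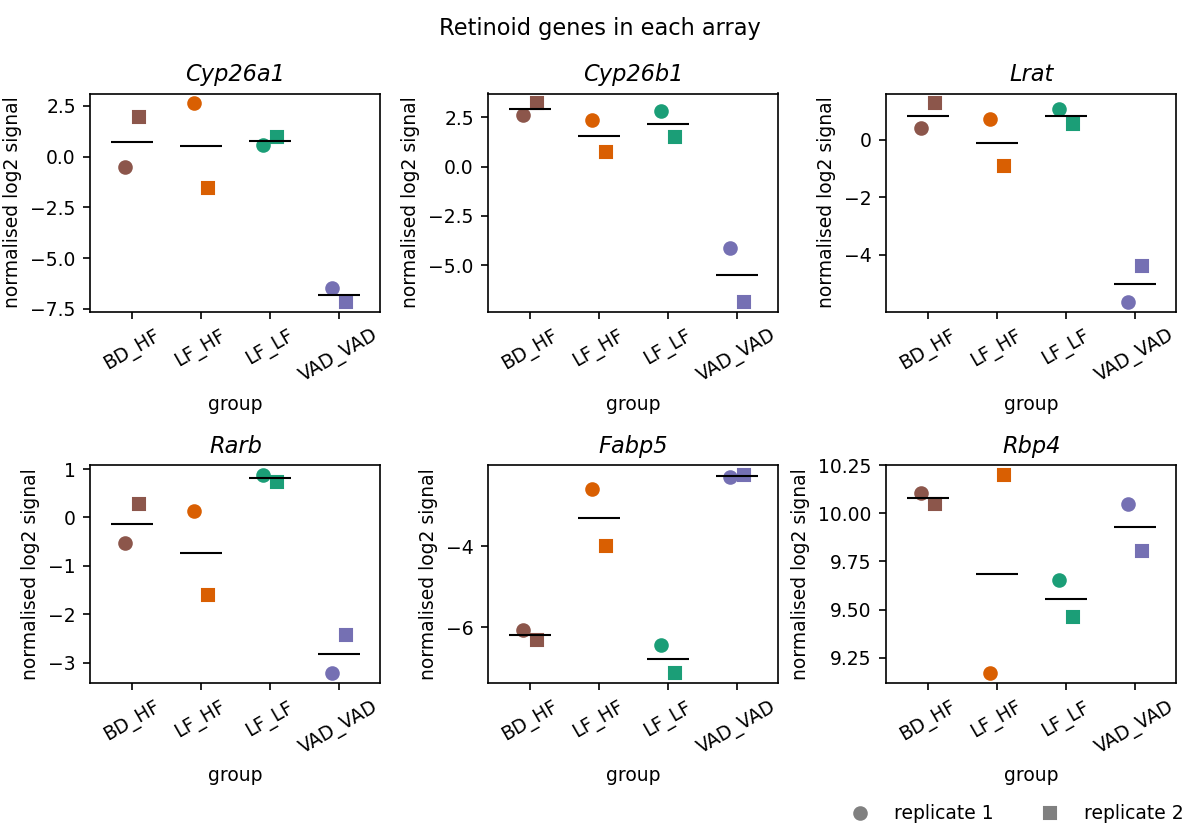
Log2 signal relative to the 75th percentile of the array for retinoid genes, 1 point per array and a line at each group mean. Lrat was −5.63 and −4.38 on the VAD_VAD arrays.

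Tinag, a basement membrane protein, fell from clear signal to below background on both deficient arrays (adjusted p = 0.0170, at least 67.1-fold). Raet1e, a stress ligand of natural killer cells, fell in the same way (adjusted p = 0.0170, at least 65.7-fold), as did Bmp8b, a bone morphogenetic protein (adjusted p = 0.0264, at least 17.4-fold), the desmosomal Pkp1 (adjusted p = 0.0469, at least 14.2-fold) and Iqgap3, a scaffold of dividing cells (adjusted p = 0.0154, at least 7.61-fold). Raet1a fell by 6.05 (SE 0.511, adjusted p = 0.0154) with 1 of 2 deficient arrays above background. Ntrk2, the receptor of brain-derived neurotrophic factor, fell by 5.17 (SE 0.674, adjusted p = 0.0324; 0.0559 with slide as a block), and Ly6d, a membrane protein induced in stressed hepatocytes, by 5.13 (SE 0.463, adjusted p = 0.0170). Gsta1 and Gsta2, glutathione transferases, fell by 3.49 (SE 0.418, adjusted p = 0.0352) and 3.95 (SE 0.487, adjusted p = 0.0264).

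Of 25 measured cell cycle genes, 0 rose, 5 fell and 20 did not pass, and 13 fell adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, fell by 4.42 (SE 0.388, adjusted p = 0.0154, 21.4-fold). Birc5, a mitotic survival factor, fell by 3.53 (SE 0.326, adjusted p = 0.0154), Ccnb2, a mitotic cyclin, by 3.51 (SE 0.339, adjusted p = 0.0161) and Mki67, a mark of cycling cells, by 3.49 (SE 0.366, adjusted p = 0.0170). The list median was −1.98, or −1.51 with signals at the bounds, and the list fell (adjusted p = 6.18e-17; adjusted p = 0.0938 with an estimated correlation). Of 24 extracellular matrix genes, 3 fell and 0 rose, and 11 fell adjusted over the list alone: Col1a1, the chain of type I collagen, fell by 3.81 (SE 0.401, adjusted p = 0.0170), Col3a1 by 3.15 (SE 0.338, adjusted p = 0.0179) and Col6a3 by 2.63 (SE 0.347, adjusted p = 0.0338; 0.0513 with slide as a block). That list had a median of −1.42 (adjusted p = 3.91e-10; adjusted p = 0.294 with an estimated correlation).

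Of 24 macrophage markers, 1 fell, Trem2, a receptor of lipid-laden macrophages, by 2.77 (SE 0.350, adjusted p = 0.0273); 1 rose and 7 fell adjusted over the list alone, and the list fell with a median of −0.72 (adjusted p = 1.01e-06; adjusted p = 0.486 with an estimated correlation). Cd163, a scavenger receptor of resident macrophages outside the lists, rose by 3.11 (SE 0.469, adjusted p = 0.0444; 0.0694 with slide as a block). Of 14 stellate cell markers, Ngfr, a neurotrophin receptor, fell by 2.65 (SE 0.360, adjusted p = 0.0352; 0.0513 with slide as a block) and Pdgfrb, the receptor of a platelet growth factor, by 2.39 (SE 0.334, adjusted p = 0.0403; 0.0588 with slide as a block); 3 fell adjusted over the list alone, and the list had a median of −0.40 (adjusted p = 0.000787; adjusted p = 0.498 with an estimated correlation). Of 9 cholangiocyte markers, the keratin Krt23 fell by 3.32 (SE 0.511, adjusted p = 0.0474; 0.0633 with slide as a block), 2 fell adjusted over the list alone, and the list had a median of −1.38 (adjusted p = 0.000276; adjusted p = 0.294 with an estimated correlation).

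Markers of blood and of other cells were higher as lists while 0 of their members passed over all genes. All 9 neutrophil markers had positive values, with S100a8, a calcium-binding alarmin, at 2.52 (adjusted p = 0.0504); 3 rose adjusted over the list alone, and the list rose with a median of 1.69 (adjusted p = 0.000282; adjusted p = 0.162 with an estimated correlation). Among 8 erythroid genes 6 rose adjusted over the list alone, with a median of 1.86 (adjusted p = 2.96e-05; adjusted p = 0.294 with an estimated correlation). The 18 hepatocyte markers were all positive with a median of 0.62 (adjusted p = 0.00220; adjusted p = 0.607 with an estimated correlation), and 14 endothelial markers had a median of 0.52 (adjusted p = 0.0208; adjusted p = 0.607 with an estimated correlation). Pancreatic acinar markers, 9 genes, had a median of 0.63 with 2 higher adjusted over the list alone (adjusted p = 0.0440; adjusted p = 0.555 with an estimated correlation). The hepatocyte call ended without VAD_VAD replicate 1 (adjusted p = 0.0622) and the endothelial call without VAD_VAD replicate 2 (0.0576). The pancreatic call ended without LF_HF replicate 1 (0.0595) or 2 (0.0810), LF_LF replicate 2 (0.132) or VAD_VAD replicate 1 (0.120).

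Slco1a1, a bile acid and steroid transporter, rose by 2.86 (SE 0.416, adjusted p = 0.0432; 0.0570 with slide as a block), and Susd4, a complement regulator with higher expression in males, by 3.43 (SE 0.422, adjusted p = 0.0264). Both belong to the 19 male-biased genes, of which 2 rose and 0 fell, 6 rose adjusted over the list alone, and the median was 0.68 (adjusted p = 1.23e-06; adjusted p = 0.486 with an estimated correlation). Of 24 bile acid genes, 1 rose, 8 rose adjusted over the list alone, and the median was 0.71 (adjusted p = 4.59e-05; adjusted p = 0.532 with an estimated correlation). Acute phase genes were positive in 25 of 25 members with a median of 1.36, 2.00 on slide 1 and 0.53 on slide 2, and 0 passed either adjustment (adjusted p = 1.23e-06; adjusted p = 0.538 with an estimated correlation). Cyp2c54 and Cyp2c37, cytochrome P450 enzymes, rose by 4.06 (SE 0.384, adjusted p = 0.0154, 16.7-fold) and 3.07 (SE 0.458, adjusted p = 0.0440; 0.0633 with slide as a block). Of 36 xenobiotic genes, 1 rose and 2 fell, 7 rose and 4 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.430).

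Lipogenesis genes, 25 in number, had a median of 0.71 with 0 past the threshold over all genes and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.000125; adjusted p = 0.532 with an estimated correlation). Scd1, a fatty acid desaturase, differed by 1.45 (SE 0.347, adjusted p = 0.179), Fasn, the fatty acid synthase, by 1.08 (SE 0.376) and Srebf1, their regulator, by −0.04 (SE 0.381). Cholesterol synthesis genes, 26 in number, had a median of 0.71, 0.01 on slide 1 and 1.16 on slide 2 (adjusted p = 0.000125; adjusted p = 0.555 with an estimated correlation). Fatty acid oxidation genes, 39 in number, had a median of 0.51, 0.81 on slide 1 and 0.16 on slide 2 (adjusted p = 0.00168; adjusted p = 0.667 with an estimated correlation), and 20 genes of glucose metabolism a median of 0.67, 0.72 on slide 1 and 0.19 on slide 2 (adjusted p = 0.0101; adjusted p = 0.607 with an estimated correlation). In these 3 lists 0 members passed either adjustment. Without VAD_VAD replicate 2 the lipogenesis (adjusted p = 0.0817) and cholesterol (0.186) calls ended, without LF_LF replicate 1 those of oxidation (0.0555) and glucose metabolism (0.0555), and without VAD_VAD replicate 1 that of oxidation (0.167). Cidea, a protein of lipid droplets, differed by −3.74 (SE 0.591, adjusted p = 0.0504), its relative Cidec by −1.75 (SE 1.37), and Cd36, a fatty acid transporter, by −0.99 (SE 0.354). Pparg, a regulator of fat storage, differed by −1.30 (SE 0.433) and the oxidation genes Cyp4a14 by 1.43 (SE 0.733) and Pdk4 by −1.57 (SE 0.780). The hormone gene Fgf21 differed by −0.33 (SE 0.862) and Saa1 by 2.30 (SE 1.67). None of these 8 passed. Cyp7a1, the first enzyme of bile acid synthesis, differed by −0.07 (SE 0.607), and its probes did not point the same way.

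Imprinted and fetal liver genes fell as a list of 15, with 2 lower adjusted over the list alone and a median of −0.66 (adjusted p = 0.00220; adjusted p = 0.486 with an estimated correlation). The remaining lists did not pass: circadian clock (adjusted p = 0.101), skeletal muscle (0.104; 0.0413 with slide as a block), lymphocyte (0.104), lipid droplet (0.302), interferon response (0.638), heat shock (0.709), unfolded protein response (0.788), female-biased genes (0.832) and adipocyte markers (0.949). Some of these passed once 1 array was left out: the clock list without LF_LF replicate 2 (0.000970) or VAD_VAD replicate 1 (0.00138), the lymphocyte list without LF_LF replicate 2 (0.0293) or VAD_VAD replicate 2 (0.0126), and the lipid droplet list without VAD_VAD replicate 1 (0.000395). Outside the lists, Acpp, an acid phosphatase, rose by 4.92 (SE 0.543, adjusted p = 0.0179, 30.3-fold), Rgs16, a fasting- and glucose-responsive regulator of G-protein signalling, by 4.89 (SE 0.542, adjusted p = 0.0179, 29.6-fold) and Rd3, a guanylate cyclase regulator, by 3.23 (SE 0.402, adjusted p = 0.0264) with 1 of 2 LF_LF arrays above background. Hsbp1l1, related to a heat shock regulator, rose by 2.94 (SE 0.403, adjusted p = 0.0373; 0.0514 with slide as a block) and the meiotic gene Tex12 by 2.90 (SE 0.434, adjusted p = 0.0440; 0.0633 with slide as a block).

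Across all genes, 16 were higher and 83 lower in the deficient group, so 16.2% of the calls were higher. That share was 29.0% after normexp background correction with the 75th percentile and 20.5% after normexp with quantile scaling. It was 29.6% with the stricter filter and 33.8% with trend and robust variances. With slide as a block, 11 were higher and 46 lower, and 53 of the 99 were called both ways. Limma called 0 genes without BD_HF replicate 1 or 2 (1368 at unadjusted p under 0.05 in each case), without LF_LF replicate 1 (856) or 2 (785), and without VAD_VAD replicate 1 (1049) or 2 (1837), and 234 higher and 687 lower without LF_HF replicate 1 or 2.

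LF_HF minus LF_LF asks what a high fat diet after weaning changes in offspring of dams on the low fat diet. Moxd1, a monooxygenase-like gene, rose from below background on both low fat arrays (adjusted p = 0.00341, at least 521-fold). Hsd3b5, a male-biased steroid dehydrogenase, rose by 8.27 (SE 0.894, adjusted p = 0.00905, 310-fold). Col1a1 fell by 4.67 (SE 0.401, adjusted p = 0.00478, 25.4-fold) and Cdc20 by 5.33 (SE 0.388, adjusted p = 0.00341, 40.2-fold). In mm9 the Moxd1 probe lay on chromosome 10 at 24022208 to 24022266 and the Col1a1 probe on chromosome 11 at 94813075 to 94813134.

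**Figure D3:**
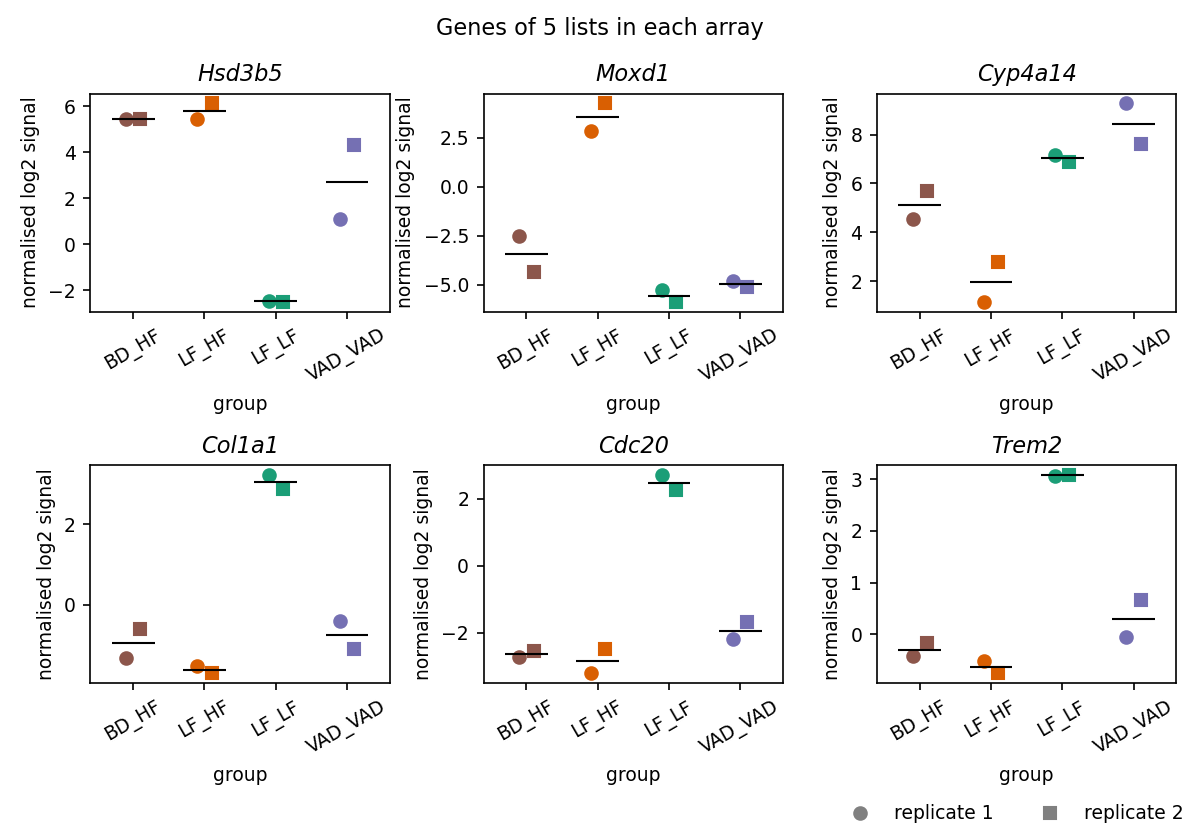
Log2 signal relative to the 75th percentile of the array for genes of the high fat and low fat groups, 1 point per array and a line at each group mean. Col1a1 was 3.22 and 2.87 on the LF_LF arrays and between −1.71 and −0.41 on the other 6.

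Of 24 extracellular matrix genes, 0 rose and 11 fell, and 18 fell adjusted over the list alone. Col3a1 fell by 3.55 (SE 0.338, adjusted p = 0.00520), Col6a3 by 3.69 (SE 0.347, adjusted p = 0.00515) with 1 of its 2 probes in that direction, and Ccn2, a matricellular growth factor, by 3.16 (SE 0.374, adjusted p = 0.0120). The list had a median of −2.09, −2.03 on slide 1 and −2.48 on slide 2 (adjusted p = 4.03e-14; adjusted p = 0.381 with an estimated correlation). Of 25 cell cycle genes, 0 rose and 9 fell, and 16 fell adjusted over the list alone. Ccnb2 fell by 4.51 (SE 0.339, adjusted p = 0.00341), Birc5 by 4.13 (SE 0.326, adjusted p = 0.00392) and Mki67 by 4.27 (SE 0.366, adjusted p = 0.00478). Their list had a median of −1.90, or −1.63 with signals at the bounds (adjusted p = 4.03e-14; adjusted p = 0.137 with an estimated correlation). Mitotic genes outside the list fell too: Cdkn3, a cyclin-dependent kinase phosphatase, by 5.86 (SE 0.454, adjusted p = 0.00374), and the spindle proteins Knstrn (adjusted p = 0.00478, at least 12.2-fold) and Nusap1 (adjusted p = 0.00719, at least 10.9-fold) to below background, Nusap1 with a value on 1 high fat array.

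Among 24 macrophage markers 5 fell and 0 rose, and 1 rose and 13 fell adjusted over the list alone: Trem2 fell by 3.71 (SE 0.350, adjusted p = 0.00515), the lysozymes Lyz2 by 2.43 (SE 0.339, adjusted p = 0.0199) and Lyz1 by 2.15 (SE 0.350, adjusted p = 0.0312), and the integrin Itgax by 3.33 (SE 0.571, adjusted p = 0.0337) with 1 of its 2 probes in that direction. The macrophage median was −1.47, −0.80 on slide 1 and −1.68 on slide 2 (adjusted p = 2.78e-07; adjusted p = 0.564 with an estimated correlation). Stellate cell markers, 14 genes, fell with a median of −1.15 (adjusted p = 9.29e-05; adjusted p = 0.564 with an estimated correlation); 2 fell, Lum, a collagen-binding proteoglycan, by 3.47 (SE 0.391, adjusted p = 0.0107) and Pdgfrb by 2.52 (SE 0.334, adjusted p = 0.0165), and 8 fell adjusted over the list alone. Endothelial markers, 14 genes, had a median of −0.81, −0.40 on slide 1 and −1.11 on slide 2, with 0 past either adjustment (adjusted p = 0.000624; adjusted p = 0.564 with an estimated correlation). Interferon response genes, 23 in number, had a median of −0.45, with 0 lower over all genes and 4 lower adjusted over the list alone (adjusted p = 0.0132; adjusted p = 0.574 with an estimated correlation). The median was −0.31 on slide 1 and −1.08 on slide 2, and −0.93 without LF_HF replicate 1, where 8 fell over all genes. The chemokine Ccl5 fell by 1.95 (SE 0.336, adjusted p = 0.0337) while the other 17 lymphocyte markers did not pass, and the bile duct keratin Krt19, with a value on 1 high fat array, fell by 2.73 (SE 0.484, adjusted p = 0.0467; 0.0719 with slide as a block). Without LF_HF replicate 2 the list calls for macrophage (adjusted p = 0.0753), stellate (0.0970), endothelial (0.251) and interferon (0.694) genes ended.

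Male-biased genes, 19 measured, had 6 higher and 0 lower, 7 higher adjusted over the list alone, and a median of 0.95 (adjusted p = 8.22e-09; adjusted p = 0.564 with an estimated correlation). That median was 0.42 on slide 1, 1.51 on slide 2 and 1.49 without LF_HF replicate 1, where 11 rose. Beside Moxd1 and Hsd3b5, Susd4 rose by 5.76 (SE 0.422, adjusted p = 0.00341) and Slco1a1 by 3.43 (SE 0.416, adjusted p = 0.0124). Hsd3b4, a relative of Hsd3b5 outside the list, rose by 7.33 (SE 0.824, adjusted p = 0.0107). Female-biased genes, 18 measured, had 0 higher and 1 lower, Ntrk2, which fell by 4.46 (SE 0.674, adjusted p = 0.0250); adjusted over the list alone 1 rose and 5 fell, and the list fell (adjusted p = 0.0315; adjusted p = 0.564 with an estimated correlation). Of 24 bile acid genes, 4 rose and 0 fell, 8 rose adjusted over the list alone, and the median was 0.58 (adjusted p = 0.000124; adjusted p = 0.574 with an estimated correlation). That median was 1.01 without LF_HF replicate 1, and 9 rose. They included Nr0b2, a repressor of bile acid synthesis, at 2.51 (SE 0.327, adjusted p = 0.0154), Akr1d1, a steroid reductase, at 1.86 (SE 0.319, adjusted p = 0.0337) and Cyp7b1, an oxysterol hydroxylase, at 2.60 (SE 0.512, adjusted p = 0.0497). Without LF_HF replicate 2 the list calls for female-biased (adjusted p = 0.428) and bile acid (0.137) genes ended. Cyp7a1 differed by −0.42 (SE 0.607, adjusted p = 0.783).

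Of 20 lipid droplet genes, 0 rose and 3 fell, 1 rose and 9 fell adjusted over the list alone, and the median was −1.16 (adjusted p = 0.00362; adjusted p = 0.581 with an estimated correlation). Cd36 fell by 2.76 (SE 0.354, adjusted p = 0.0147), Lpl, which releases fatty acids from lipoproteins, by 3.31 (SE 0.442, adjusted p = 0.0243) with a value on 1 high fat array, and Plin4, a lipid droplet coat protein, by 2.87 (SE 0.502, adjusted p = 0.0352). Cidec (−5.22, SE 1.37, adjusted p = 0.114), Cidea (−2.55, SE 0.591, adjusted p = 0.0799) and Pparg (−0.52, SE 0.433) did not pass. Of 39 fatty acid oxidation genes, 1 fell, also adjusted over the list alone: Cyp4a14, a fatty acid hydroxylase, by 5.04 (SE 0.733, adjusted p = 0.0224). The oxidation list had a median of −0.31, −0.55 on slide 1 and 0.07 on slide 2 (adjusted p = 0.0384; adjusted p = 0.865 with an estimated correlation), and without LF_HF replicate 1 it turned to a median of 0.20 that did not pass (adjusted p = 0.725); it did not pass without LF_LF replicate 2 either (0.226). Pdk4 (−2.24, SE 0.780) and Fgf21 (−2.99, SE 0.862) did not pass. Among 25 lipogenesis genes, Thrsp, a lipogenic nuclear protein, rose by 3.46 (SE 0.468, adjusted p = 0.0181) and the desaturase Scd2 fell by 3.08 (SE 0.401, adjusted p = 0.0154), the same 2 members adjusted over the list alone, and the list did not pass (adjusted p = 0.439). Scd1 (−1.29, SE 0.347, adjusted p = 0.122), Fasn (0.17, SE 0.376) and Srebf1 (0.66, SE 0.381) did not pass. Cholesterol synthesis genes, 26 in number, rose as a list with a median of 0.85, or 0.57 without LF_HF replicate 1, and 0 members past either adjustment (adjusted p = 0.00286; adjusted p = 0.715 with an estimated correlation). Without LF_HF replicate 2 the calls for lipid droplet (0.0905) and cholesterol (0.0905) genes ended, and the cholesterol call also without LF_LF replicate 2 (0.0540).

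Imprinted and fetal liver genes fell as a list of 15 with a median of −0.50, −0.27 on slide 1 and −0.94 on slide 2 (adjusted p = 0.0124; adjusted p = 0.564 with an estimated correlation); H19, a fetal noncoding RNA, fell by 2.87 (SE 0.464, adjusted p = 0.0302) and Afp, the fetal serum protein, by 1.94 (SE 0.308, adjusted p = 0.0287), and 3 fell adjusted over the list alone. In the retinoid handling list Fabp5 rose from below background (adjusted p = 0.0204, at least 4.79-fold), while the list (adjusted p = 0.943) and the retinoic acid targets (adjusted p = 0.439) did not pass. Among 36 xenobiotic genes, 1 rose and 4 fell, and 6 rose and 12 fell adjusted over the list alone: Cyp2c54 rose by 5.82 (SE 0.384, adjusted p = 0.00341, 56.5-fold), while Gsta2 fell by 4.0 (SE 0.487, adjusted p = 0.0127), Srxn1, an antioxidant reductase, by 2.50 (SE 0.305, adjusted p = 0.0129) and Gsta1 by 3.28 (SE 0.512, adjusted p = 0.0337), with a value on 1 high fat array. The xenobiotic list did not pass (adjusted p = 0.227). Pancreatic acinar markers rose as a list of 9 with a median of 0.97, 1.76 on slide 1 and 0.75 on slide 2 (adjusted p = 0.00286; adjusted p = 0.564 with an estimated correlation): the pancreatic proteases Cela2a and Ctrc rose by 2.27 (SE 0.386, adjusted p = 0.0336) and 2.12 (SE 0.356, adjusted p = 0.0325), and 3 rose adjusted over the list alone. Skeletal muscle markers rose as a list of 10 with a median of 0.51, 2.37 on slide 1 and 0.20 on slide 2 (adjusted p = 0.00286; adjusted p = 0.564 with an estimated correlation); the myosin Myh2 rose by 3.83 (SE 0.702, adjusted p = 0.0401), and 2 rose adjusted over the list alone. Without LF_HF replicate 1 the pancreatic (median 0.53, adjusted p = 0.212) and muscle (median −0.04, adjusted p = 0.870) calls ended, and without LF_HF replicate 2 the imprinted call (0.631).

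The remaining lists did not pass: circadian clock (adjusted p = 0.149), hepatocyte (0.196), cholangiocyte (0.202), adipocyte (0.330), acute phase (0.439), unfolded protein response (0.439), neutrophil (0.449), heat shock (0.556), lymphocyte (0.568), glucose metabolism (0.784) and erythroid genes (0.996). Without LF_HF replicate 1, lists rose for hepatocyte (0.000129), acute phase (0.000258), unfolded protein (0.00139) and glucose metabolism genes (0.0431, from a negative direction), and the cholangiocyte list fell (0.00169). The lymphocyte list rose without LF_HF replicate 2 (0.0158) and the clock list without LF_LF replicate 2 (0.00754). Saa1, an acute phase protein, differed by 0.72 (SE 1.67), and was 4.19 on LF_HF replicate 1 and 8.68 on replicate 2. Among the other large rises were Capn8, a stomach calpain (at least 21.9-fold), Irx1, a developmental homeobox gene (at least 21.1-fold), Obp2a, a lipocalin (at least 14.3-fold), and Wif1, an inhibitor of Wnt ligands (at least 11.7-fold), all from below background on both LF_LF arrays, with adjusted p of 0.00423, 0.0236, 0.00341 and 0.00341. Cyp2c37 rose by 4.94 (SE 0.458, adjusted p = 0.00491). Among the other large declines, Ly6d fell by 7.24 (SE 0.567, adjusted p = 0.00491), and the endothelial proteoglycan Esm1 by 5.93 (SE 0.761, adjusted p = 0.0209), each with a value on 1 high fat array. The protease inhibitor Wfdc3 fell by 5.14 (SE 0.428, adjusted p = 0.00465), with 1 of 2 high fat arrays above background. Ubd, a ubiquitin-like modifier induced by cytokines, fell by 5.21 (SE 0.607, adjusted p = 0.0120), and Tinag fell to below background (adjusted p = 0.00520, at least 48.9-fold).

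Across all genes, 107 were higher and 325 lower in LF_HF, so 24.8% of the 432 calls were higher. That share was 61.2% after normexp background correction with the 75th percentile, and 21.2% after normexp with quantile scaling. With slide as a block 119 were higher and 235 lower, and 317 were called both ways. Without BD_HF replicate 1 or 2 there were 40 higher and 70 lower, without VAD_VAD replicate 1 or 2 45 higher and 108 lower, and without LF_LF replicate 2 7 higher and 10 lower. Limma called 0 genes without LF_LF replicate 1 (1459 at unadjusted p under 0.05). Without LF_HF replicate 1 there were 408 higher and 1507 lower, which kept 431 of the 432, and without LF_HF replicate 2 there were 2644 higher and 1579 lower. The number of lists called, 15, dropped to 7 without LF_HF replicate 2. In simulated data with 200 changed genes, 28.2% of the calls in this comparison were false. That share depends on the number and size of the simulated changes and is not an estimate for the 432 calls.

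The 2 comparisons against LF_LF share its arrays. Over the 16248 genes with a value on every array their differences correlated at 0.556, against a mean of 0.133 and a highest of 0.162 in 100 simulated draws without effects. The covariance was 0.437 against a simulated mean of 0.0318, a difference of 0.406. On these genes 12 were higher and 53 lower in both, where independent lists would share 0.0867 and 0.969. With 2 LF_LF arrays the controls were not split, and the draws held no deviation common to both. Part or all of the excess may therefore come from their sharing. Over all tested genes 69 were lower in both, among them Col1a1, Cdc20, Trem2, Tinag and Ly6d, and 12 were higher in both, among them Cyp2c54, Susd4, Slco1a1 and Fabp5.

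BD_HF minus LF_HF asks what the maternal diet changes in offspring that all received the high fat diet. Tmem150b, a membrane protein linked to autophagy, was the only gene past the threshold: it fell to below background on both BD_HF arrays (adjusted p = 0.0297), at least 4.75-fold. Moxd1, the gene that rose most against LF_LF, differed by −7.00 on the log2 scale (SE 0.690, adjusted p = 0.113) and did not pass. Tmem150b was also lower in VAD_VAD than in LF_HF (limma adjusted p = 0.0189), with 0 VAD_VAD arrays above background. The lower value was therefore not particular to BD_HF. That pair of groups was chosen after the results were seen. The Tmem150b probe lay on chromosome 7 at 4658619 to 4658678 in mm9. With slide as a block Tmem150b did not pass (adjusted p = 0.0852), nor without LF_HF replicate 1 (adjusted p = 0.0802).

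The other genes named for this comparison did not pass. Scd1 differed by 1.79 (SE 0.347, adjusted p = 0.786), 1.55 on slide 1 and 2.02 on slide 2. Hamp2, a hepcidin gene, differed by 2.72 (SE 0.518), and the melanosome adaptor Mlph was above background on 1 of 4 arrays. The homeobox gene Rhox5, with a value on 1 LF_HF array, and the imprinted antisense transcript Copg2os2 were above background on 0 LF_HF arrays, at least 11-fold and 3.02-fold higher in BD_HF (both adjusted p = 0.786). Dmrta1, a transcription factor (adjusted p = 0.461), the glutamate receptor Grm8 (adjusted p = 0.786) and Fabp5 (adjusted p = 0.786) were above background on 0 of 2 BD_HF arrays, at least 4.57-fold, 6.82-fold and 3.28-fold lower. Cyp4a14 differed by 3.15 (SE 0.733), Cd36 by 1.33 (SE 0.354), Cidec by 0.94 (SE 1.37) and Pdk4 by 0.91 (SE 0.780). Fasn differed by 0.65 (SE 0.376), Srebf1 by 0.55 (SE 0.381) and Cyp7a1 by 0.47 (SE 0.607). Negative values were those of Cidea at −0.32 (SE 0.591), Fgf21 at −0.35 (SE 0.862), Pparg at −0.63 (SE 0.433) and Saa1 at −1.97 (SE 1.67). Of the imprinted and fetal genes named beforehand, Afp differed by −0.43 (SE 0.308) and H19 by 0.04 (SE 0.464) with probes that did not point the same way, and Igf2 was above background on 1 of 4 arrays.

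Over all genes 0 members of any list passed in this comparison. Endothelial markers, 14 genes, rose as a list with a median of 1.30, 0.78 on slide 1 and 1.89 on slide 2, and 10 rose adjusted over the list alone (adjusted p = 1.20e-08; adjusted p = 0.522 with an estimated correlation). They included the scavenger receptor Stab2 at 1.33, the liver sinusoidal lectin Clec4g at 1.62 and Oit3 at 1.72. Fatty acid oxidation genes rose in the same way, with 38 of 39 positive, a median of 0.57, 0.92 on slide 1 and 0.36 on slide 2, and 4 higher adjusted over the list alone (adjusted p = 3.48e-08; adjusted p = 0.801 with an estimated correlation). Without LF_HF replicate 1 that median was 0.15 (adjusted p = 0.0244). Among them were the acyl-CoA thioesterases Acot3 at 2.68 and Acot4 at 1.42, and the pantetheinase Vnn1 at 1.63. Lipogenesis genes, 25 in number, rose with a median of 0.55, or 0.27 without LF_HF replicate 1, and 1 higher adjusted over the list alone, Scd1 (adjusted p = 0.000360; adjusted p = 0.801 with an estimated correlation). Female-biased genes, 18 in number, rose with a median of 0.75 and 2 higher adjusted over the list alone, Cyp2b9, a cytochrome P450 at 4.68, and Acot3 (adjusted p = 0.000854; adjusted p = 0.522 with an estimated correlation). Male-biased genes, 19 in number, fell with a median of −0.30, 0.10 on slide 1 and −0.70 on slide 2, and 1 lower adjusted over the list alone, Moxd1 (adjusted p = 0.0154; adjusted p = 0.804 with an estimated correlation). Their median was −0.77 without LF_HF replicate 1 (adjusted p = 4.46e-09). The male-biased call ended without BD_HF replicate 1 (adjusted p = 0.0628) and took a positive direction without LF_HF replicate 2 (0.617), and the female-biased call ended without LF_HF replicate 2 (0.265). So did the lipogenesis call without LF_HF replicate 1 (0.050).

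Neutrophil markers, 9 genes, fell with a median of −1.74 (−1.41 with signals at the bounds), −2.31 on slide 1 and −1.13 on slide 2, and 3 fell adjusted over the list alone: the chemokine receptor Cxcr2 at −4.38, the collagenase Mmp8 at −3.95 and Retnlg, a resistin-like secreted protein, at −1.74 (adjusted p = 3.76e-05; adjusted p = 0.262 with an estimated correlation). Erythroid genes, 8 in number, rose with a median of 0.98, or 1.5 without LF_HF replicate 1, and 4 higher adjusted over the list alone, among them the globins Hba-a1 at 1.61 and Hbb-bt at 1.65 (adjusted p = 0.0182; adjusted p = 0.801 with an estimated correlation). Pancreatic acinar markers, 9 genes, fell with a median of −1.26, or −0.62 with signals at the bounds, −1.59 on slide 1 and −0.09 on slide 2, with 2 lower adjusted over the list alone, Cela2a at −1.40 and Ctrc at −1.45 (adjusted p = 0.00485; adjusted p = 0.801 with an estimated correlation). For 5 more lists 0 members passed either adjustment. Skeletal muscle markers fell with a median of −0.66, or −0.72 with signals at the bounds, −1.35 on slide 1 and −0.03 on slide 2 (adjusted p = 0.0136; adjusted p = 0.801 with an estimated correlation). Xenobiotic genes rose with a median of 0.42, 0.72 on slide 1 and 0.21 on slide 2 (adjusted p = 0.0154; adjusted p = 0.801 with an estimated correlation), and stellate cell markers with a median of 0.51, 0.38 and 0.82 on the slides (adjusted p = 0.0154; adjusted p = 0.801 with an estimated correlation). Circadian clock genes rose with a median of 0.53, 0.72 and 0.31 on the slides (adjusted p = 0.0405; adjusted p = 0.801 with an estimated correlation). Glucose metabolism genes rose with a median of 0.47, 0.79 and 0.12 on the slides (adjusted p = 0.0182; adjusted p = 0.804 with an estimated correlation), and the direction of the test turned to lower without LF_HF replicate 1 (median 0.02, adjusted p = 0.334). Without LF_HF replicate 1 the calls ended for pancreatic (median −0.03, adjusted p = 0.248), muscle (0.08, 0.648), xenobiotic (0.06, 0.708) and clock genes (0.33, 0.334), each with its median and adjusted p. Without LF_HF replicate 2 the erythroid (0.298), stellate (0.601) and clock (0.265) calls ended, and without BD_HF replicate 2 the muscle (0.163), xenobiotic (0.163), stellate (0.189), clock (0.136) and glucose (0.161) calls.

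The remaining lists did not pass: lymphocyte (adjusted p = 0.0572), extracellular matrix (0.0596), unfolded protein response (0.0596; 0.0413 with slide as a block), interferon response (0.125), heat shock (0.190), hepatocyte (0.223), lipid droplet (0.240), bile acid (0.329), macrophage (0.339), imprinted and fetal (0.374), adipocyte (0.376), cholangiocyte (0.378), cholesterol synthesis (0.394), acute phase (0.441), retinoic acid targets (0.579), retinoid handling (0.857) and cell cycle (0.978). Without LF_HF replicate 1, lists rose for interferon (2.95e-05), macrophage (0.000105), extracellular matrix (0.00134) and retinoic acid target genes (0.0163) and fell for acute phase (2.45e-07) and hepatocyte genes (0.0141). Without LF_HF replicate 2, lists rose for unfolded protein (0.00354), hepatocyte (0.00891) and heat shock genes (0.0350), and the lymphocyte list fell (0.00354). Other calls of this kind came without BD_HF replicate 1 for lymphocyte (0.0420), extracellular matrix (0.00787) and lipid droplet genes (0.0189), and without BD_HF replicate 2 for cholesterol synthesis (0.000190). They came without VAD_VAD replicate 1 or 2 for extracellular matrix (0.0466 each), and without LF_LF replicate 1 (0.0454) or 2 (0.0455) for unfolded protein genes. Across all genes 0 were higher and 1 lower by limma, with 945 at unadjusted p under 0.05, and 0 passed with slide as a block (1328). Limma called 0 without BD_HF replicate 1 (514 at unadjusted p under 0.05) or 2 (329), without LF_HF replicate 1 (1501), without LF_LF replicate 1 or 2 (527 each) and without VAD_VAD replicate 1 or 2 (797 each). Without LF_HF replicate 2, which left the array with raised signal alone, 598 were higher and 2435 lower.

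**Figure D4:**
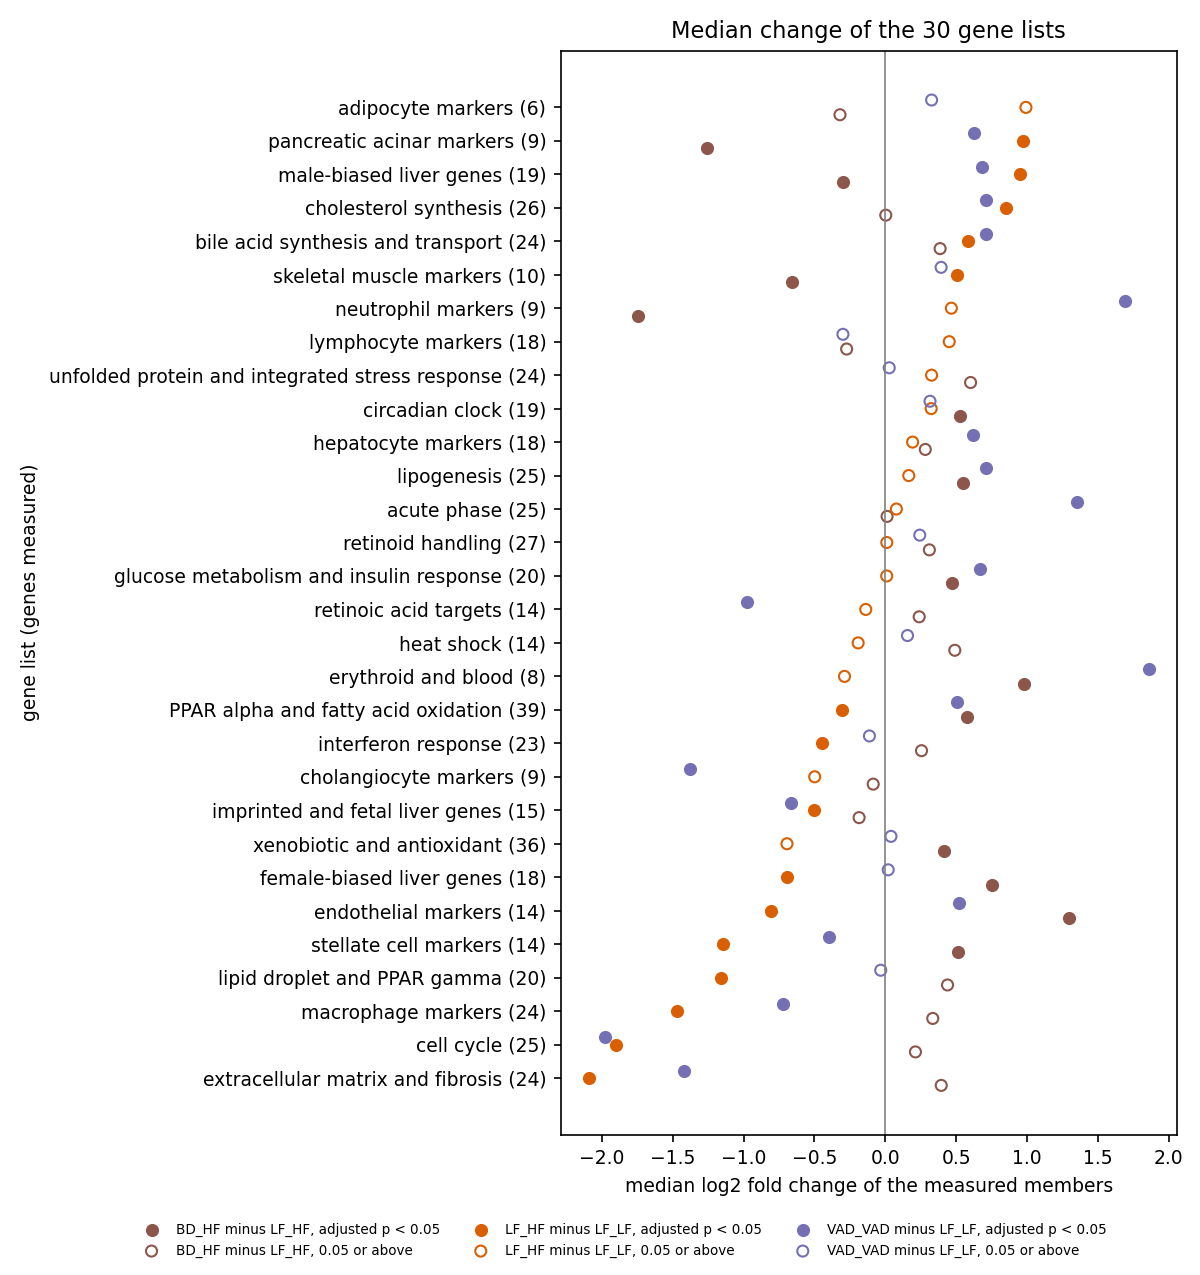
Median log2 difference of the measured members of each of the 30 gene lists in the 3 comparisons, with filled points where the adjusted p at the preset correlation was under 0.05. Extracellular matrix genes lay at −2.09 in LF_HF minus LF_LF and at −1.42 in VAD_VAD minus LF_LF, which share the LF_LF arrays.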

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

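The comparison of dim probes with negative controls was chosen only after the result was seen; the tests of base composition and of genomic DNA were written before.

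Negative-control spots, which match no mouse transcript and are not used in the comparisons, had a mean raw signal of 74.5 on LF_HF replicate 1, above the 24.3 to 28.9 of the other 7 arrays. Dim gene probes, those not well above background on any of the other 7 arrays, rose more. Their median raw signal exceeded that of the negative controls by 54.8 on this array and by 2.19 to 3.62 on the others. The selection did not use LF_HF replicate 1 and favours small gaps on the other 7, so the contrast between arrays is partly fixed by it. The gap within this array argues against an equal offset of the whole scan. The gain of X-linked over autosomal dim probes had a ratio of 1.09 (95% interval 0.983 to 1.21), which argues against genomic DNA from a male in the labelled sample. Across dim probes, raw signal followed the share of G and C bases with a Spearman rho of 0.581, against 0.184 to 0.269 on the other arrays, so hybridization that depends on base composition may account for the raised signal; no biological explanation was tested.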

How the results depend on the processing

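Cyclic loess and array weights were chosen only after the results were seen, and the other settings were planned. With 2 arrays per group, array weights gave both arrays of a group the same weight, 0.195 in LF_HF and 3.28 in LF_LF. That setting therefore could not single out LF_HF replicate 1.

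Counts of genes are given as higher and lower. For BD_HF minus LF_HF the 1 lower gene became 0 (limma) with quantile scaling, cyclic loess, no filter, the filter on all arrays, the block, the 4 compared arrays alone and array weights; in that order 1259, 1285, 1122, 772, 1328, 393 and 313 passed an unadjusted p under 0.05, against 945 as reported. For LF_HF minus LF_LF, 107 and 325 became 1596 and 1013 with normexp and the 75th percentile, 285 and 1059 with normexp and quantile scaling, 311 and 1002 with cyclic loess, and 10 and 22 with no filter. They became 0 and 0 (limma, 1871 unadjusted against 2885 as reported) on the 4 compared arrays alone, 212 and 595 with trend and robust variances, 220 and 581 at adjusted p under 0.10, and 10 and 10 with array weights. The lower count was 694 with quantile scaling and 201 with the mean of probes, and the higher count 164 with the filter on all arrays. For VAD_VAD minus LF_LF, 16 and 83 became 104 and 255 with normexp and the 75th percentile, 71 and 276 with normexp and quantile scaling, 82 and 305 with cyclic loess, and 0 and 0 with no filter (limma, 1492 unadjusted against 1789 as reported). They became 87 and 412 on the 4 compared arrays alone, 101 and 198 with trend and robust variances, 55 and 175 at adjusted p under 0.10, and 373 and 799 with array weights. The higher count was 47 with the filter on all arrays, and the lower count 52 with the mean of probes.

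The replicate number coincides with the slide, so the replicate block and the slide block are the same fit, with 46 lower in VAD_VAD minus LF_LF and 0 lower in BD_HF minus LF_HF. The labels give the numbers no meaning, and correlations of replicate differences between groups ran from 0.0994 to 0.304, so the samples share a number without being shown to be pairs. The block ended 0 of the list calls and added 1, 0 and 1 in the order above; it changed no call of a named gene beyond those printed with a block value.

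Lists called in BD_HF minus LF_HF numbered 13, and became 8 with quantile scaling, 8 with cyclic loess, 21 with no filter, and 0 with an estimated correlation or with fry. The 15 of LF_HF minus LF_LF became 0 and 2, and the 19 of VAD_VAD minus LF_LF 0 and 1, in those last settings; fry, which tests a list against no change, called cell cycle in both (0.00302 and 0.00516) and extracellular matrix in the former (0.0144).

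With 1 array left out, counts of higher and lower genes ranged from 0 to 598 and 0 to 2435 in BD_HF minus LF_HF, 0 to 2644 and 0 to 1579 in LF_HF minus LF_LF, and 0 to 234 and 0 to 687 in VAD_VAD minus LF_LF. Lists called ranged from 7 to 17 in LF_HF minus LF_LF.

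Among lists called as reported or in the alternative, directions turned in 5 pairs of list and comparison; where neither was called, they turned in 22, 17 and 10 of 240 values with 1 array left out and in 30, 27 and 30 of 507 in other settings. In BD_HF minus LF_HF, glucose metabolism turned with quantile scaling (adjusted p = 0.892) and without LF_HF replicate 1, where leaving out 1 array gave 0.00502 to 0.334. There male-biased genes turned without LF_HF replicate 2 (4.46e-09 to 0.617) and hepatocyte genes without LF_HF replicate 1 (0.00891 to 0.529, at 0.0141 without that array). In LF_HF minus LF_LF, oxidation genes (0.00342 to 0.725) and glucose metabolism (0.0431 to 0.993) turned without LF_HF replicate 1. Of named genes, 0 turned as called values. With 1 array left out 173 of 514 values in LF_HF minus LF_LF and 210 of 416 in VAD_VAD minus LF_LF lost the call. The 514 and 416 include named genes not called as reported, which had no call to lose. In VAD_VAD minus LF_LF every called named gene lost its call without either array of BD_HF, LF_LF or VAD_VAD.

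The median of all genes was 0.17, −0.02 and 0.09 in the order of the comparisons. In LF_HF minus LF_LF it moved to −0.29 with quantile scaling and −0.13 after normexp with quantile scaling, and with no filter the 3 medians were −0.23, 0.49 and 0.24. In BD_HF minus LF_HF it was 0.06 and in VAD_VAD minus LF_LF −0.04 with cyclic loess.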

Other observations

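All tests weighed in this part, and the further pairs of groups, were chosen only after the results were seen.

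Against both high fat groups 0 of the retinoid genes looked at in VAD_VAD passed. Against BD_HF, Cyp26b1 differed by −8.42 (SE 0.948, adjusted p = 0.0744) and Lrat by −5.84 (SE 0.662, adjusted p = 0.0744), and against LF_HF by −7.05 (adjusted p = 0.0691) and −4.90 (adjusted p = 0.0691). Both genes were above background on 1 of 2 VAD_VAD arrays, so the size of these differences rests in part on signal near background. The retinoic acid target list fell against BD_HF (median −0.81, adjusted p = 6.93e-07; adjusted p = 0.162 with an estimated correlation). Neutrophil markers rose against BD_HF with a median of 3.44 (adjusted p = 4.23e-12; adjusted p = 0.0469 with an estimated correlation), where limma called 0 genes (1025 at unadjusted p under 0.05). The extracellular matrix list was higher in VAD_VAD than in BD_HF (median 0.24, camera adjusted p = 0.00299, or 0.919 with an estimated correlation). So was the cell cycle list (median 0.30, camera adjusted p = 0.0198, or 0.919 with an estimated correlation). Against LF_HF 4 genes were higher and 11 lower, and 6 of the 15 passed with slide as a block. Among the 15 were Cyp4a14, a fatty acid hydroxylase (6.46, adjusted p = 0.0426; 0.078 with slide as a block), Ccn2, a matricellular growth factor (4.0, adjusted p = 0.0356), and Moxd1 (−8.51, adjusted p = 0.0189).

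BD_HF minus LF_LF, which differs in both maternal and later diet, called 79 genes higher and 183 lower, and 246 with slide as a block. Hsd3b5 rose by 7.93, Cyp2c54 by 6.27, Rgs16 by 5.50 and Thrsp by 3.89, and Cdc20 fell by 5.11. The cell cycle list (median −2.65, adjusted p = 1.74e-20; adjusted p = 0.0656 with an estimated correlation) and the extracellular matrix list (median −1.83, adjusted p = 3.53e-17; adjusted p = 0.261 with an estimated correlation) fell.

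The LF_LF arrays stood apart from the other 3 groups in matrix, proliferation and macrophage genes. The covariance of the 2 comparisons that use them, 0.437, lay above the highest simulated value of 0.0389. The simulated noise was scaled to the spread between replicates, so the covariance exceeded what sharing that noise would give. A deviation common to both LF_LF arrays was not in the draws, and sharing it cannot be told apart from an effect of the groups. A lower hepatocyte share in LF_LF would raise markers of all other cell types there alike. The intervals given for marker lists come from resampling the genes of a list, not the arrays. They do not measure variation between samples, and members of a list can vary together. Medians of endothelial and macrophage markers lay 1.81 apart in BD_HF minus LF_LF (95% interval 0.733 to 2.42) and 1.24 apart in VAD_VAD minus LF_LF (0.839 to 2.03). For these arrays alone, that argues against a lower hepatocyte share as the whole cause in those 2 comparisons. In LF_HF minus LF_LF they lay 0.664 apart (−0.223 to 1.17), with endothelial markers at −0.81, so it cannot be told apart. Hepatocyte markers over the other groups lay at 0.41 (0.286 to 0.765), in the direction of a lower share. An exchange of the LF_LF and LF_HF labels cannot be told apart from correct labels: on 384 genes BD_HF lay at 0.177 and VAD_VAD at 0.409 on a scale from 0 at LF_HF to 1 at LF_LF, so each lay nearer to the group labelled LF_HF. Diet and vitamin A intake stay open as untested causes. The lower collagen, Cd36 and Cyp4a14 values in LF_HF than in LF_LF hold for the groups as labelled. Against LF_LF, Col1a1 was also lower in BD_HF (−4.01) and in VAD_VAD on the low fat diet (−3.81). BD_HF lay above LF_HF by 1.33 in Cd36 and by 3.15 in Cyp4a14, and neither difference passed.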
